A study of Homo sapiens with 6 samples.

How the data were processed

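RNA was measured in 6 libraries of HL60 cells, a human promyelocytic leukaemia line kept in culture, 3 treated with 250 nM cytarabine (AraC, a cytidine analogue that is built into DNA and stalls its synthesis) for 1 day and 3 treated with the solvent DMSO. Per the labels' protocols, cells were stained with Pyronin Y (an RNA dye) and Hoechst (a DNA dye), the G0/G1 fraction was sorted by flow cytometry, 400 ng of total RNA was enriched for poly(A) RNA on oligo-dT beads, and libraries were sequenced as paired-end reads on a NovaSeq instrument. The labels do not say whether G0 and G1 cells were kept apart, and the protocol also speaks of Pyronin-Y high and low cells, so a difference in the share of G0 cells between the groups would enter the cell cycle, quiescence and ribosome values. The labels call the replicates biological and number them 1 to 3 in both groups. They do not say whether they came from separate cultures or days, so the p-values measure the spread between these samples.

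The values analysed are the deposited counts, whole-number counts of reads per gene that the authors did not normalise. Per the submitters' processing notes, cutadapt, STAR and featureCounts were used with the hg38 build, with versions of cutadapt and STAR not given in the sources used here. Per the file headers, counts were made with featureCounts 2.0.6 on the GENCODE 44 annotation, in paired-end mode with the strand option 2. The headers record no option to count a pair as 1 fragment, and between 66.6% and 71.9% of the counts from 1 to 20 in each library were even numbers, so the deposited counts are of reads, with the mates of a pair mostly counted separately. An evenly inflated count makes counting error look smaller than it is. The fit was therefore also run on halved counts.

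The strand option was tested on the data. Genes were taken whose overlap with exons of a coding gene on the other strand, summed over all exon records, exceeded 95% of their length. Their median read density was 0.862 to 0.918 of that of the host gene across the 6 libraries, over 293 to 484 gene pairs. A library that keeps strand would hold far fewer reads on the opposite strand. Records repeated between transcripts were counted more than once, so genes only partly inside a host could enter, and their own reads may raise the density. The check therefore does not settle whether these libraries separated the strands. It was taken as possible that reads of a gene and of its antisense or overlapping partner cannot be told apart. For each gene, the share of its reads that opposite-strand genes could supply was estimated with bedtools 2.31.1 from the deposited coordinates. An even read density along each partner was assumed. Overlaps were summed over all partners and, as above, over repeated exon records, with the share capped at all reads of the gene. A share can therefore be too high, and the partner named is the one with the largest estimated contribution. Genes above 20% are named as uncertain below. Genes with near-identical copies (CCL3L3, CCL4L2 and the histone families) are uncertain because reads of the copies may not be told apart. All 62700 gene identifiers matched a symbol, and all 6 columns of per-sample values belong to the samples. Gene types came from GENCODE 29, which held 58207 of the identifiers.

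The only contrast is AraC against DMSO control. Counts were tested in R 4.3.3 with edgeR 4.0.16, with filterByExpr, TMM scaling and the quasi-likelihood F test (robust), without a replicate term, and Benjamini-Hochberg adjustment over the 17773 genes kept. Genes with an adjusted p under 0.05 are said to have risen or fallen. These words mean a change relative to the other transcripts of a library, and a change in total RNA per cell would not be seen. The TMM factors were 1.0375 to 1.0623 in the AraC libraries and 0.9407 to 0.963 in the controls. Levels are CPM (reads scaled to library size, in the usual unit) after TMM scaling, as mean ± SD over the 3 libraries of a group, and log2 fold changes are AraC minus DMSO control with their standard error (SE). The 31 gene lists, the design, the rule for named genes and most of the alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, correlation 0.01), again with the correlation estimated from the data, and with fry, adjusted over the 31 lists. Camera compares a list with the other genes, while fry tests whether the genes of a list move on balance in 1 direction.

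The rule for named genes had 3 parts. The first took the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM, groups that do not overlap and a regular gene symbol. The second took from each list the 2 called genes with the largest increase and the 2 with the largest decrease, or the member with the lowest p where none was called. The third was CDKN1A, GDF15, MYC, SLC29A1, DCK, CDA, SAMHD1, MKI67, CCND1, CCND2 and CCND3. It gave 118 genes. Genes named outside it were chosen after their values were seen and are marked so where they appear.

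The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter beyond a total above 0, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. The alternatives added after seeing the data left out the genes missing from AraC replicate 2 alone, left out the genes above 20% possible opposite-strand reads, or halved the counts. Coordinates are those of the deposited table (hg38). Sex-linked genes on chromosome Y and the X-inactivation transcripts were left out of the result tables. A result of a further gene group is not reported here. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for reading and plotting.

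The edgeR step was tested on simulated counts with the means, spread and library sizes of AraC against DMSO control. Of 200 changed genes among 17773, it called 35.8% of those changed 1.5-fold, 64.2% of those changed 2-fold and 84.8% of those changed 4-fold, with 14 false calls. In the camera step, a list of 30 genes shifted by 0.5 on the log2 scale was called, and of 30 unshifted lists 0 were called. The simulated genes were independent of each other, so this does not test how camera behaves with correlated genes.

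Depth was 24656395 to 38834845 counted reads per library. A count of 3 reads corresponds to 0.0773 CPM in the deepest library and 0.1217 CPM in the shallowest, and intervals on ratios of reads cover counting error only. Pairs of libraries within a group differed by far more than sampling noise, with a chi-square per gene of 6.56 to 29.3 over genes with at least 20 reads, so all 6 were counted as separate samples.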

Results

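The series asks how acute myeloid leukaemia cells respond to cytarabine at the level of transcription, and its title links rapid transcription dynamics to resistance. Gene expression was measured by poly(A) RNA-seq in sorted G0/G1 HL60 cells after 1 day with 250 nM AraC (3 libraries) or with DMSO (3 libraries). The AraC libraries held 28902597, 38834845 and 24656395 counted reads for replicates 1 to 3 and the controls 31401721, 26776323 and 27916541. Between 25114 and 25543 genes had at least 1 read per library. Mitochondrial transcripts took 2.12% to 2.74% of the reads in the AraC libraries and 1.93% to 2.12% in the controls. The 50 most abundant genes took at most 13.9% of the reads in the AraC libraries and at least 15.1% in the controls, and EEF1A1 led in all 6 libraries. Pearson's r of log2 CPM, computed across genes, was 0.984 to 0.989 between controls and 0.963 to 0.985 between AraC libraries. Across groups it was 0.942 to 0.969, so AraC replicates 2 and 3 (0.963) were less alike than some pairs across groups.

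In AraC replicate 2, 270 genes that had at least 0.5 CPM in each of the other 5 libraries stood more than 8-fold below their lowest level there. The same rule gave 0 to 4 genes for each of the other libraries. These genes summed to 17.5 CPM in AraC replicate 2, against 611 and 825 CPM in the other AraC libraries and 796 to 841 CPM in the controls. Of the 270, edgeR called 0 higher and 0 lower, with 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. They include GDF15, GPNMB, CCN2, CD44 and NT5C3B among the members of the gene lists, named here after their values were seen.

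**Figure D1:**
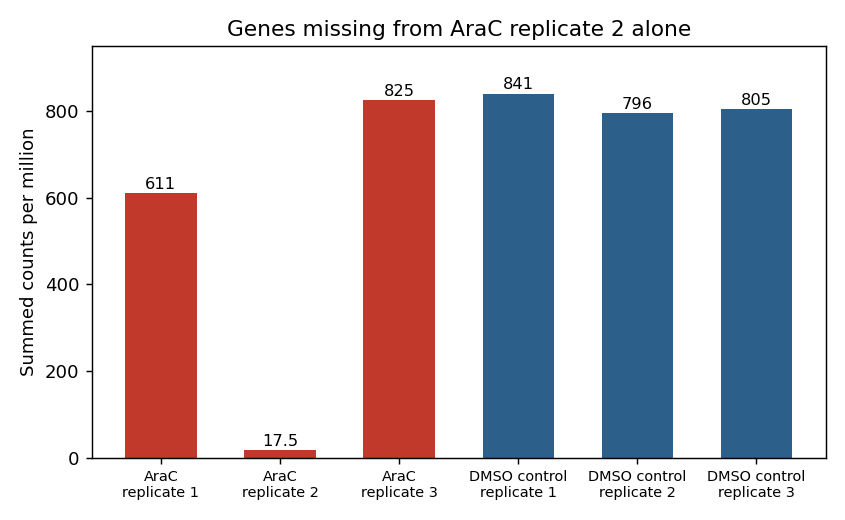
Summed CPM (vertical axis, from 0) of the 270 genes missing from AraC replicate 2 alone, in each of the 6 libraries (1 bar per library, red for AraC, blue for DMSO control). AraC replicate 2 stands at 17.5 CPM and the other 5 libraries at 611 to 841 CPM, in both groups.

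After a day of AraC many inflammatory and neutrophil maturation transcripts and the cell cycle inhibitor CDKN1A were higher, and most integrated stress response and ribosomal protein transcripts were lower. With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 2570 genes rose and 2252 fell among 17773 tested. Increases were larger: 916 genes rose at least 2-fold and 248 fell at least 2-fold. The groups did not overlap for 99.3% of the called genes and 44.3% of the tested genes, where chance gives 10%. The number of genes that fell was 1381 without AraC replicate 1 and 1339 without control replicate 2. Of the 31 gene lists, camera with a preset correlation called 8 higher and 5 lower. With the correlation estimated from the data it called 0, with 4 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.18, while fry called 9 higher and 4 lower. The list calls therefore depend on whether camera used a preset or an estimated correlation. What part the correlation itself plays in this was not tested, and a gene group below had a larger adjusted p although its estimated correlation lay under the preset.

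Among the 10 largest increases of genes with a mean of at least 5 CPM were 5 chemokine genes. CCL4, a monocyte and lymphocyte attractant (chromosome 17, 36103827 to 36105621), rose from 0.502 ± 0.221 to 20.3 ± 5.88 CPM, a log2 fold change of 5.31 ± 0.33. CXCL8, the neutrophil attractant interleukin 8 (chromosome 4, 73740519 to 73743716), rose from 9.22 ± 4.02 to 115 ± 10.9 CPM. CCL3L3 and CCL4L2 rose by log2 4.35 ± 0.15 and 3.58 ± 0.19, but each shares reads with near-identical copies. CCL3 rose by 4.10 ± 0.77, and some or all of its reads could come from the antisense transcript CCL3-AS1. The CCL3 call was lost without control replicate 1 (edgeR adjusted p = 0.0609), in limma-voom (0.0668) and without a count filter (0.0642). CDKN1A, the inhibitor of cyclin-dependent kinases known as p21 (chromosome 6, 36676460 to 36687337), rose from 7.80 ± 2.20 to 168 ± 44.3 CPM (log2 4.43 ± 0.27, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.000119). The short-chain fatty acid receptor FFAR2 rose by 4.16 ± 0.25, the hexokinase HK3 by 3.72 ± 0.21, the adhesion receptor ADGRG5 by 3.69 ± 0.34 and the integrin ITGAM, known as CD11b, by 3.30 ± 0.18, from 3.78 ± 0.788 to 37.2 ± 6.11 CPM.

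Among genes with a mean of at least 5 CPM, the 10 largest decreases were smaller on the log2 scale than the 10 largest increases. The amino acid transporter SLC7A5 (chromosome 16, 87830023 to 87869507) fell from 750 ± 172 to 230 ± 6.31 CPM and the stress transcription factor ATF5 (chromosome 19, 49928702 to 49933935) from 725 ± 149 to 199 ± 38.1 CPM. Their log2 fold changes were -1.71 ± 0.16 and -1.87 ± 0.18. The glycine transporter SLC6A9 had -1.76 ± 0.29, the linker histone H1-10 -1.73 ± 0.13, the DNA helicase PIF1 -2.04 ± 0.21, the transcription factor GMEB1 -1.65 ± 0.12 and the sodium/proton exchanger SLC9A8 -1.63 ± 0.11. GDAP1L1 had -2.29 ± 0.52, and its call was lost without AraC replicate 1 or without any of the 3 controls (edgeR adjusted p 0.054 to 0.0891). NDUFA4L2 had -2.50 ± 0.28 and H1-10-AS1 -1.73 ± 0.09. Some or all reads of each could come from the opposite-strand genes SHMT2 and H1-10, which both fell. For ATF5 and SLC6A9 the estimated opposite-strand share was 29.2% and 52.9%.

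**Figure D2:**
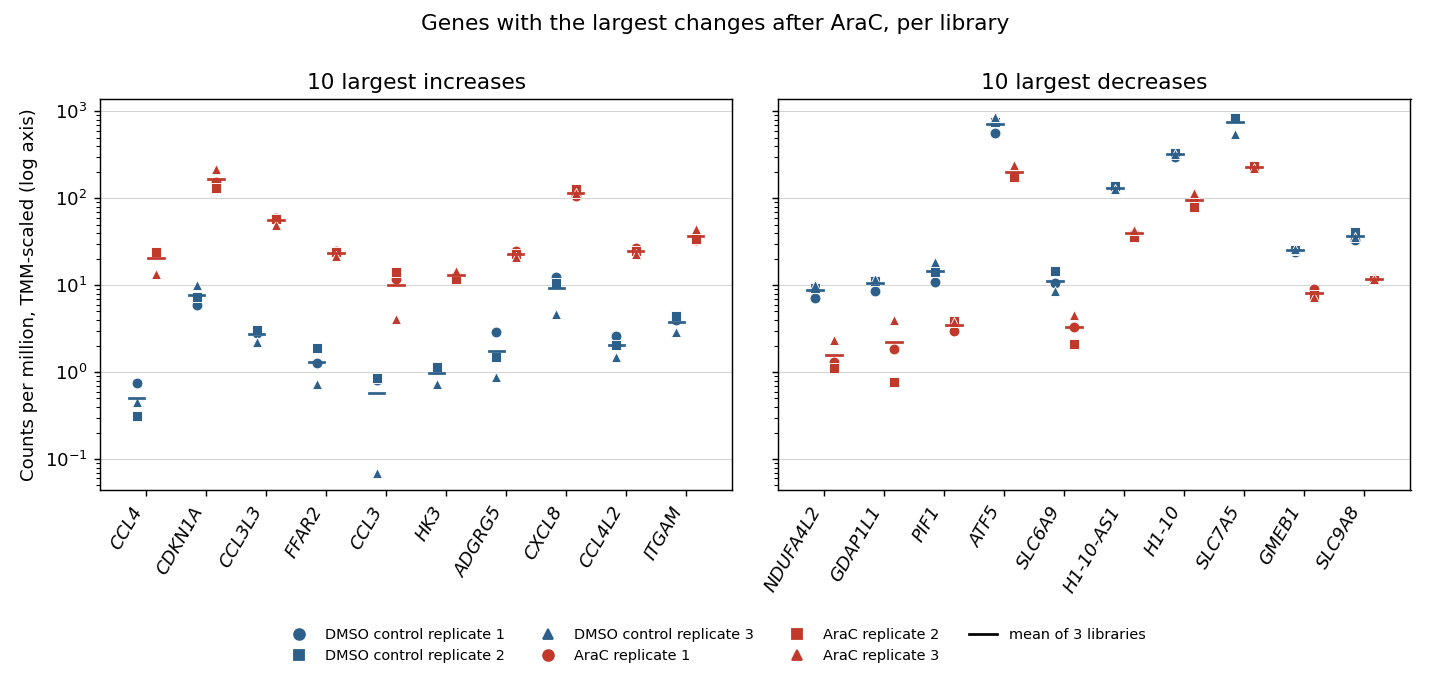
TMM-scaled CPM (vertical log axis) of the 10 genes with the largest increases (left) and the 10 with the largest decreases (right) among genes with a mean of at least 5 CPM. Each point is a library, red for AraC and blue for DMSO control with the shape giving the replicate, and bars are means of 3. CDKN1A goes from a mean of 7.80 to 168 CPM and SLC7A5 from 750 to 230 CPM, with no overlap of the groups for any of the 20 genes.

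Cell cycle genes did not move together. Of 47 genes of DNA replication and the G1/S transition, 26 rose and 4 fell (29 and 4 adjusted over the list alone), with camera adjusted p = 2.27e-06 and adjusted p = 0.3 with an estimated correlation. CCNE2, a cyclin of S-phase entry, rose by log2 1.97 ± 0.16, from 16.6 ± 3.32 to 65.4 ± 8.92 CPM, although up to 81.5% of its reads could come from INTS8. Thymidine kinase TK1 rose by 1.12 ± 0.09, from 89.1 ± 5.71 to 194 ± 18.1 CPM. The replication licensing factor CDT1 and the kinase regulator DBF4 fell by 0.79 and by 0.37. The CDT1 call was lost without AraC replicate 1 or 2 or control replicate 2 or 3 (edgeR adjusted p 0.0596 to 0.124), and the DBF4 call without each library other than AraC replicate 2 (0.0752 to 0.123). The number that fell was 0 without AraC replicate 1 or control replicate 2 and 1 without control replicate 1. Of 38 mitosis and G2/M genes, 15 fell and 2 rose (17 and 2 adjusted over the list alone), with camera adjusted p = 7.16e-05 and adjusted p = 0.67 with an estimated correlation. The mitotic kinesin KIF20A fell by 1.06 on the log2 scale and securin, PTTG1, by 0.87. The mitotic kinase CDK1 rose by 0.39 ± 0.09. FOXM1 rose by 0.32 ± 0.09, a call lost without 4 of the libraries (AraC replicates 1 and 2, control replicates 1 and 2, edgeR adjusted p 0.0763 to 0.144), and some or all of its reads could come from ITFG2. In these 4 fits the number that rose was 1. The proliferation marker MKI67 did not pass the test, at 395 ± 18.8 CPM after AraC and 464 ± 79.9 CPM in the controls.

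Replication-dependent histone transcripts, which normally end without a poly(A) tail and are made in S phase, were low in these poly(A) libraries. Of 57 genes 24 could be tested and 12 fell, with none of the 24 called higher by edgeR (12 fell adjusted over the list alone). The list median was -1.48 on the log2 scale, with camera adjusted p = 2.27e-06 and adjusted p = 0.43 with an estimated correlation. H2BC13 fell from 2.82 ± 1.02 to 0.187 ± 0.103 CPM. H2AC8 had 88 reads over the 3 controls and 5 over the 3 AraC libraries, a ratio of 20.8 with a 95% exact binomial counting interval of 8.6 to 65.8, which is too narrow because the mates of a pair were counted separately. These genes are near-identical copies, so their reads may be split unevenly. Of 31 genes of quiescence and cell cycle exit, 9 fell and 4 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.192). The pocket protein RBL1 fell by 0.80 and the transcription factor FOXO4 by 0.93. HES1, a Notch target, rose by 0.93 ± 0.20. SESN3 rose by 0.94 ± 0.23, a call lost without control replicate 2 (edgeR adjusted p = 0.0555). The D-type cyclins differed from each other. CCND3 rose from 227 ± 10.6 to 358 ± 19.6 CPM and CCND1 from 66.9 ± 6.59 to 91.6 ± 0.875 CPM. CCND2 was 178 ± 8.10 CPM in the controls and 149 ± 22.8 CPM after AraC, which did not pass the test with all libraries (edgeR adjusted p = 0.117) but did without AraC replicate 2 (0.0298) and with the replicate block (0.0267).

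Of 30 p53 target genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). CDKN1A led, followed by the antiproliferative BTG2, which rose from 4.68 ± 0.712 to 27.4 ± 1.91 CPM (log2 2.55 ± 0.14). The leucine sensor SESN2 fell from 102 ± 25.4 to 43.3 ± 12 CPM, a call lost with the replicate block (edgeR adjusted p = 0.0873). The list passed the preset camera test narrowly (adjusted p = 0.043) and did not with an estimated correlation (adjusted p = 0.43), without AraC replicate 3 (0.0687), without control replicate 1 (0.0741) or with the replicate block (0.0528). It also missed the threshold without genes open to opposite-strand reads (0.0643) and with halved counts (0.0525). GDF15, a stress cytokine and p53 target, was 18.6 ± 18.5 CPM after AraC and 19.0 ± 1.83 CPM in the controls. It stood at 17.7, 0.54 and 37.5 CPM in AraC replicates 1, 2 and 3, and it is among the genes missing from AraC replicate 2 alone. Of 47 DNA damage checkpoint and repair genes, 12 rose and 7 fell (14 and 8 adjusted over the list alone, camera adjusted p = 0.276). The exonuclease EXO1 rose by 0.89 ± 0.09 and the helicase BRIP1 by 0.57 ± 0.09, while the histone variant H2AX fell by 0.86 and the mitosis-restraining kinase WEE1 by 0.62. The counts were 9 and 4 without AraC replicate 1 and 7 and 5 without control replicate 2. In the BCL2 family, 5 of 16 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.171). The survival gene BCL2A1 rose from 6.31 ± 0.723 to 19.7 ± 4.33 CPM and the death-promoting BIK from 3.11 ± 0.538 to 8.50 ± 1.56 CPM. The number of BCL2 family genes that fell was 2 without AraC replicate 3. HRK, also death-promoting, fell from 1.47 ± 0.817 to 0.198 ± 0.196 CPM, a call lost without AraC replicate 1, control replicate 2 or control replicate 3 (edgeR adjusted p 0.0853 to 0.106) and with the replicate block (0.0519).

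Most inflammatory transcripts in the NF-kappaB list and 16 of 32 interferon-stimulated transcripts rose. Of 28 NF-kappaB and inflammatory cytokine genes, 20 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 1.23 on the log2 scale. Camera gave adjusted p = 3.95e-09, and adjusted p = 0.36 with an estimated correlation. Its largest increases were CCL4 and CCL3, given above. SOD2, a mitochondrial antioxidant enzyme, fell by 0.25, and this call was lost without any 1 of the libraries other than AraC replicate 2 (edgeR adjusted p 0.055 to 0.108) and without a count filter (0.0761). Up to 24.4% of its reads could come from WTAP. Of 32 interferon-stimulated genes, 16 rose and 16 did not pass the test (20 rose adjusted over the list alone), with a median of 1.39. Camera gave adjusted p = 3.17e-08, and adjusted p = 0.49 with an estimated correlation. The antiviral TRIM22 rose from 1.25 ± 0.0755 to 12 ± 5.77 CPM. IFI44 rose from 0.916 ± 0.575 to 6.14 ± 3.98 CPM, a call lost without control replicate 1 or 2 (edgeR adjusted p 0.0575 to 0.0907) and in limma-voom (0.06). The number of interferon-stimulated genes that rose was 8 without AraC replicate 1, 8 without control replicate 1 and 26 with the replicate number as a block.

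Most neutrophil maturation transcripts rose, and other myeloid lists were more mixed. Of 18 neutrophil maturation genes, 13 rose and 5 did not pass the test (17 rose adjusted over the list alone), with a median of 1.61. Camera gave adjusted p = 3.72e-09, and adjusted p = 0.18 with an estimated correlation. ITGAM led, and the granule protease MMP9 rose from 0.358 ± 0.0979 to 2.32 ± 1.05 CPM. Of 24 monocyte and macrophage genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 0.00094 and adjusted p = 0.3 with an estimated correlation. The fractalkine receptor CX3CR1 rose from 0.246 ± 0.16 to 2.31 ± 0.595 CPM. The inhibitory receptor LILRB1 rose from 0.13 ± 0.113 to 0.854 ± 0.124 CPM, a call lost without AraC replicate 1 (edgeR adjusted p = 0.0762). CD4 fell from 332 ± 33.3 to 215 ± 5.66 CPM. The number of these genes that rose was 14 with the replicate block and 13 without a count filter. Of 18 primary granule and promyelocyte genes, 3 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.183). Myeloperoxidase, MPO, fell from 4780 ± 1010 to 2460 ± 350 CPM, while the granule protein BPI rose by 1.54 ± 0.16 and NKG7 by 1.95 ± 0.13. PLPPR3 fell by 0.66, a call lost without each of 5 libraries (all but control replicate 3, edgeR adjusted p 0.0502 to 0.11) and in limma-voom (0.0507). The number that fell was 1 without AraC replicate 2 or 3 or control replicate 1 or 2, and the number that rose was 5 without control replicate 3. With DESeq2 or without a count filter 7 rose and 3 fell, with the replicate block 6 and 4, and with limma-voom 4 and 1. Of 18 stem and progenitor genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.849), with a median of -0.05 and a mean of 0.13. The ectoenzyme CD38 rose by 1.31 ± 0.24. The transcription factors MYB and LMO2 fell by 0.87 and by 0.58, though up to 53.5% of the MYB reads could come from MYB-AS1. SPINK2 rose from 0.215 ± 0.107 to 1.08 ± 0.687 CPM, a call lost without AraC replicate 3, control replicate 2 or control replicate 3 (edgeR adjusted p 0.0555 to 0.0894).

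Most integrated stress response and ribosomal protein transcripts fell. Of 28 integrated stress response genes, 26 fell and 2 did not pass the test (28 fell adjusted over the list alone), with a median of -1.15. Camera gave adjusted p = 1.17e-14, and adjusted p = 0.34 with an estimated correlation. ATF5 and SLC7A5, given above, fell most. Of 78 cytosolic ribosomal protein genes, 68 fell and 10 did not pass the test (69 fell adjusted over the list alone), with a median of -0.43. Camera gave adjusted p = 3.14e-17, and adjusted p = 0.43 with an estimated correlation. RPL12 fell from 1480 ± 177 to 794 ± 111 CPM and RPL10A from 1250 ± 99.6 to 711 ± 74.8 CPM. The number of ribosomal protein genes that fell was 44 without AraC replicate 1 and 44 without control replicate 2. Of 37 ribosome biogenesis and RNA polymerase I genes, 16 fell and 21 did not pass the test (16 fell adjusted over the list alone), and 10 fell without control replicate 2. Camera gave adjusted p = 2.97e-05, and adjusted p = 0.66 with an estimated correlation. Nucleophosmin, NPM1, fell from 2770 ± 154 to 1580 ± 172 CPM and WDR43 from 179 ± 9.20 to 99.1 ± 12.1 CPM. MYC, a transcription factor that drives ribosome production, fell from 869 ± 141 to 395 ± 58.5 CPM (log2 -1.14 ± 0.14; edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.000534; chromosome 8, 127735434 to 127742951). Of 20 heat shock protein genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.183). The co-chaperones DNAJA1 and BAG3 rose by 1.02 ± 0.16 and 0.94 ± 0.12. HSP90AB1 and the mitochondrial HSPA9 fell by 0.36 and by 0.39, and both calls were lost without AraC replicate 1 or control replicate 1 or 2 (edgeR adjusted p 0.0502 to 0.0907). The number that rose was 3 without AraC replicate 1, and camera called the list without AraC replicate 3 (adjusted p = 0.0177). With the replicate block 11 rose and 3 fell.

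Of 23 cholesterol synthesis and uptake genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with camera adjusted p = 0.000431 and adjusted p = 0.61 with an estimated correlation. The sterol reductase TM7SF2 rose from 16.6 ± 1.72 to 47.7 ± 7.86 CPM. The isomerase IDI1 rose from 28.3 ± 5.72 to 56.2 ± 3.95 CPM, with up to 28.2% of its reads open to IDI2-AS1. SREBF2, the transcription factor that drives this pathway, fell from 295 ± 20.6 to 194 ± 5.23 CPM. The number that rose was 9 without AraC replicate 1, 9 without AraC replicate 3, 8 without control replicate 2 and 7 without control replicate 3. Of 75 nuclear-encoded oxidative phosphorylation genes, 5 rose and 7 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.75), and these counts were 2 and 6 without AraC replicate 1, 5 and 4 without control replicate 1, and 3 and 4 without control replicate 2. They were 10 and 8 with the replicate block and 9 and 8 without a count filter. The ATP synthase genes ATP5MC1 and ATP5MC2 went in opposite directions, by 0.62 ± 0.13 and -0.74 ± 0.09. NDUFA8 of complex I rose by 0.59 ± 0.12 and UQCRC2 of complex III fell by 0.60. Of 13 mitochondrially encoded mRNAs, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.643). MT-ND2 fell by 0.47. The call of MT-ND1 (0.35 ± 0.09) was lost without control replicate 2, that of MT-CO3 (0.39 ± 0.11) without AraC replicate 3 or control replicate 1 or 2, and that of MT-ND3 (-0.29 ± 0.09) without AraC replicate 1 or 2 or control replicate 1 or 2 (edgeR adjusted p 0.0551 to 0.136). The number that rose was 2 without control replicate 1 and 0 without control replicate 2. Of 24 glycolysis genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.848), with a median of -0.03 and a mean of 0.11. These counts were 4 and 5 with DESeq2, 5 and 5 without a count filter and 5 and 6 with the replicate block. After HK3, the regulator PFKFB3 rose most, by 0.88 ± 0.09. HK2 fell by 0.62, and ALDOA fell by 0.65, though some or all of the ALDOA reads could come from an opposite-strand gene.

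The enzymes and transporters that handle AraC itself went both ways. Of 25 genes of cytarabine uptake and nucleotide metabolism, 8 rose and 3 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.192). The uptake transporter SLC29A1 and the activating kinase DCK did not pass the test, although SLC29A1 did with the replicate block (log2 0.19, edgeR adjusted p = 0.045). SLC29A1 was 278 ± 30.9 CPM after AraC and 244 ± 37.8 CPM in the controls, and DCK 47.2 ± 0.615 and 41.5 ± 0.589 CPM. SAMHD1, which hydrolyses the active triphosphate, rose from 29.9 ± 6.71 to 64.6 ± 10.6 CPM (log2 1.11 ± 0.18; edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.00262), with up to 27.8% of its reads open to TLDC2. Cytidine deaminase, CDA, which inactivates AraC, rose from 1.84 ± 1.38 to 7.78 ± 4.46 CPM. Its edgeR adjusted p was 0.0472 and rose to between 0.0671 and 0.171 without AraC replicate 1 or 3 or control replicate 1 or 2, and to 0.0579 without a count filter. The nucleotidases NT5C and NT5C3A fell by 0.63 and by 0.60, though some or all NT5C reads could come from an opposite-strand gene. The number that rose was 5 without AraC replicate 1 and 5 without control replicate 2, while the number that fell was 5 with DESeq2, the replicate block or no count filter. Of 9 ABC efflux transporters 2 rose (2 adjusted over the list alone, camera adjusted p = 0.662). These were ABCC5 (0.36 ± 0.10) and ABCC1 (0.32 ± 0.10), and both calls were lost without AraC replicate 1 or 2 or control replicate 2 or 3, and that of ABCC1 also without control replicate 1 (edgeR adjusted p 0.0512 to 0.157).

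Immediate-early genes, many of them with unstable transcripts, changed both ways. Of 37 genes, 11 rose and 3 fell (13 and 3 adjusted over the list alone), and camera just missed its threshold (adjusted p = 0.0539, and 0.0412, 0.0434 and 0.02 without AraC replicate 1, control replicate 1 and control replicate 2). Without the genes missing from AraC replicate 2, CCN2 among them, it was 0.0417. The list stayed uncalled without any 1 of the other libraries, and had a camera adjusted p of 0.683 with an estimated correlation. JUN rose from 17.1 ± 2.28 to 82.6 ± 21.3 CPM (log2 2.27 ± 0.19) and BTG2 as given above. MYC fell, and CCN1 fell from 2.53 ± 0.340 to 0.864 ± 0.451 CPM, a call lost without control replicate 2 (edgeR adjusted p = 0.0748). The counts were 9 and 5 without AraC replicate 2, 7 and 2 without control replicate 2, and 8 and 5 without control replicate 3. Of 39 genes of transcription pausing and elongation, 11 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.183), and 7 fell without AraC replicate 1 or control replicate 1. HEXIM1, an inhibitor of the elongation kinase P-TEFb, was the gene that rose, from 56.5 ± 4.96 to 99.1 ± 6.76 CPM. The elongation factor TCEA1 and the pausing factor NELFA fell by 0.61 and by 0.54. Fry, which does not compare the list with other genes, called this list lower (adjusted p = 0.00233). Of 37 RNA polymerase II subunits and general factors, 5 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.662), and these were 3 and 2 without AraC replicate 1 and 4 and 2 without control replicate 2. TAF13 and GTF2H5 rose by 0.67 ± 0.12 and 0.56 ± 0.13, and GTF2F2 and TAF4 fell by 0.49 and by 0.44. Of 32 Mediator genes, 2 rose and 3 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.421), and these were 0 and 2 without AraC replicate 1 or control replicate 2. MED16 fell by 0.68 and CDK8 by 0.39. MED27 and MED31, at 0.42 ± 0.11 and 0.79 ± 0.21, were the rising genes whose calls were lost (edgeR adjusted p 0.0594 to 0.0795 in those fits). A call of a gene that fell was lost there too. Some or all MED31 reads could come from TXNDC17. Of 34 mRNA deadenylation and decay genes, 10 fell and 2 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.16), and 6 fell without AraC replicate 1 or control replicate 2. BTG1 fell by 0.71 and the deadenylase CNOT6 by 0.59, and TOB1 rose by 0.57 ± 0.12.

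**Figure D3:**
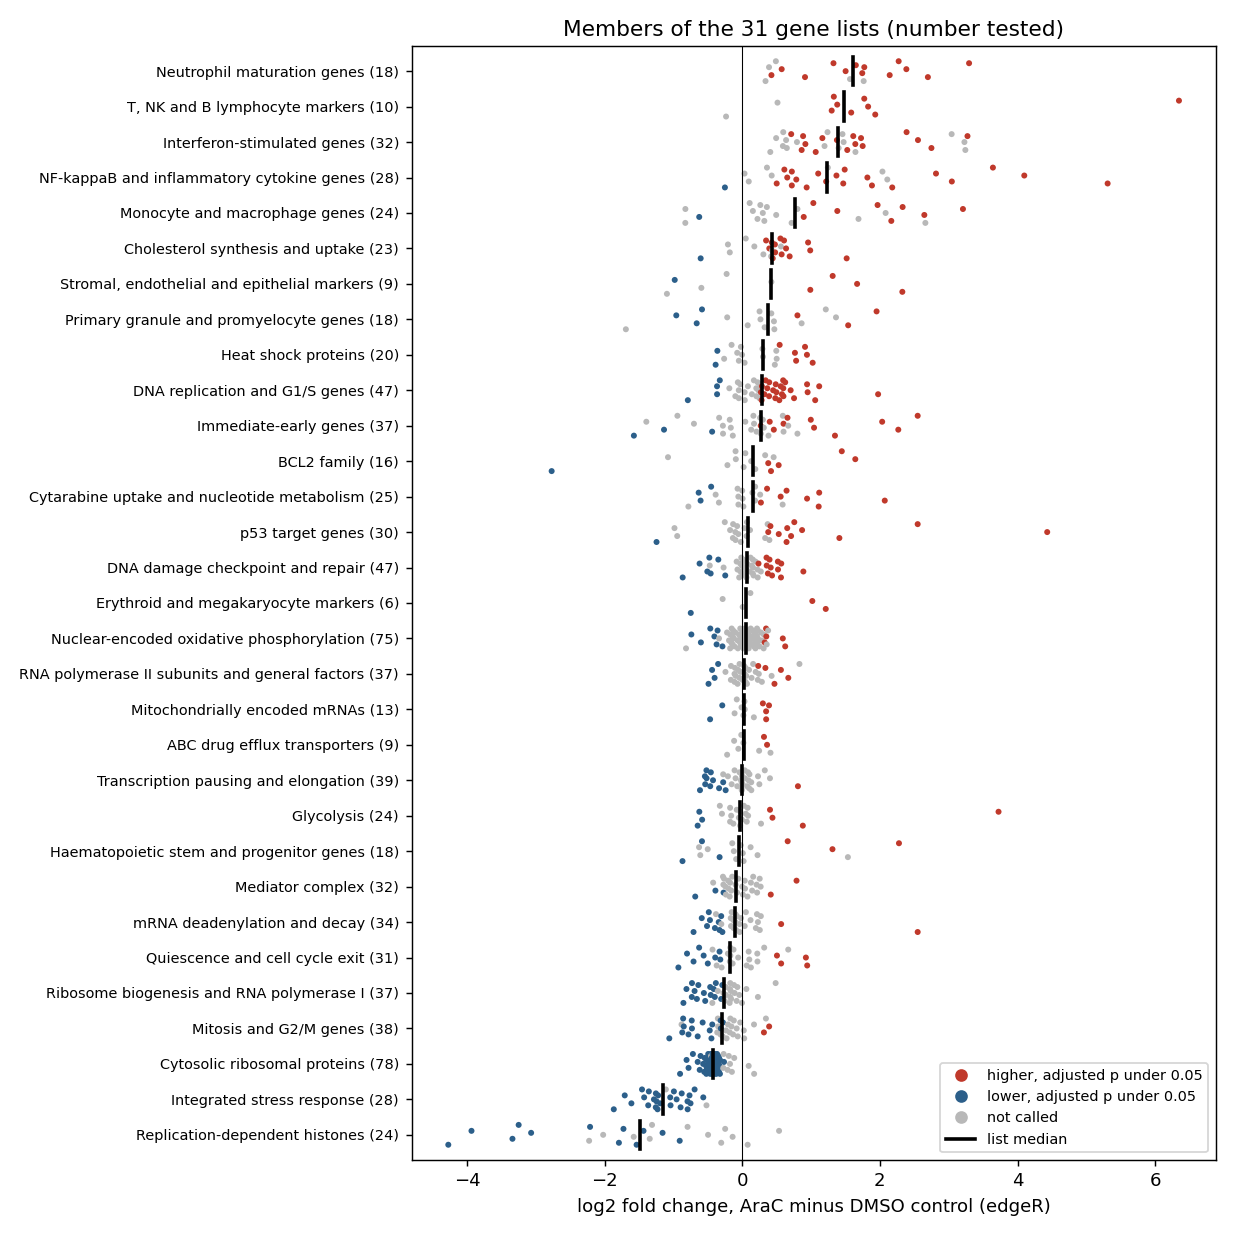
log2 fold changes (horizontal axis, AraC minus DMSO control) of the tested members of the 31 gene lists, 1 row per list with the number tested, ordered by median (black bar). Red and blue points are genes called higher and lower by edgeR, and grey points were not called. The histone and integrated stress response lists have the lowest medians (-1.48 and -1.15) and the neutrophil maturation list the highest (1.61).

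Markers of other cell types were checked in the sorted cells. Of 23 T, NK and B lymphocyte markers 10 could be tested and 8 rose (8 adjusted over the list alone), with camera adjusted p = 2.97e-05 and adjusted p = 0.3 with an estimated correlation. The T-cell receptor constant gene TRAC (chromosome 14, 22547506 to 22552156) rose from 9.59 ± 0.857 to 36.6 ± 2.60 CPM. CD79B, a B-cell receptor component, had 122 reads over the 3 AraC libraries and 1 read over the 3 controls, a ratio of 103 with a 95% exact binomial counting interval of 18.2 to 4100, too narrow for the same reason as above. Of 6 erythroid and megakaryocyte markers tested, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.845). The transferrin receptor TFRC rose from 120 ± 30.6 to 243 ± 34.9 CPM and EPOR fell by 0.75. ITGA2B rose by 1.21 ± 0.31, a call lost without control replicate 1 or 2 (edgeR adjusted p 0.0552 to 0.0576). Of 9 stromal, endothelial and epithelial markers tested, 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.536). ACTA2 rose by 1.67 ± 0.33, with up to 96.3% of its reads open to ACTA2-AS1. COL1A1 rose to 1.57, 7.55 and 1.53 CPM in AraC replicates 1, 2 and 3 from 0.715 ± 0.151 CPM, a call lost without AraC replicate 2 or any control and in limma-voom. COL1A2 fell by 0.98, a call lost without AraC replicate 1 or 3 or control replicate 1 or 2 (edgeR adjusted p 0.0601 to 0.167 for these 2 genes in those fits).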

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

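The alternatives that left out the genes missing from AraC replicate 2, left out the genes open to opposite-strand reads or halved the counts were chosen after seeing the data. Under DESeq2, limma-voom, RLE and upper-quartile scaling, both filters, the block and these 3 alternatives, the counts of genes stayed within 1.5 times of those reported, and every gene called both there and in the reported fit had the same sign. An adjusted p under 0.01 left 1452 genes higher, 1142 lower and 132 lower by at least 2-fold, which follows from the stricter threshold. With 1 library left out, the number of genes lower ranged from 1339 to 2101, higher from 1724 to 2522, at least 2-fold higher from 752 to 987 and at least 2-fold lower from 174 to 326. Camera with the estimated correlation called 0 lists higher and 0 lower, with 4 at an unadjusted p under 0.05, where fry called 9 and 4. Fry did not call mitosis (0.0911), ribosome biogenesis (0.0759) or cholesterol (0.0669), and called cytarabine metabolism (0.0107), the BCL2 family (0.0232) and transcription elongation (0.00233). The cause was not tested. RLE and upper-quartile scaling moved the median log2 fold change by -0.007 and 0.002. Of the 118 named genes GDF15 changed sign, from -0.06 to 0.53 without AraC replicate 2, and passed the test in neither fit (edgeR adjusted p = 0.978 and 0.2). In the fits that held them, no other named gene changed sign. The number that lost their call was 24 without control replicate 2, 17 without AraC replicate 1, 16 without control replicate 1, 7 to 9 without each of the others, 4 in limma-voom, 3 without a filter and 27 at an adjusted p under 0.01.

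The replicate numbers were checked for pairing. Deviations from the group means, over all genes tested, correlated at 0.093, 0.038 and 0.144 between same-numbered libraries. These low values neither show nor exclude pairing, so the replicate block was kept as an alternative only. Each AraC library correlated best with the control of its own number over all tested genes. AraC replicate 2 did not once the genes missing from it were left out (0.037, against 0.044 with control replicate 1), nor did AraC replicate 1 over the interferon-stimulated genes (-0.127, against 0.394 with control replicate 2), where replicates 2 and 3 matched their own number best (0.611 and 0.516). With the replicate block 3075 genes were higher, 2707 lower, 940 at least 2-fold higher and 241 at least 2-fold lower, and 7 lists were higher and 5 lower, the p53 target list being lost (adjusted p = 0.0528). Genes with few reads, such as CD79B and H2AC8, are limited by depth.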

Other observations

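The gene groups in the first 2 paragraphs and the tests below were chosen after the results were seen, except those of B-cell precursors, of RNA without a poly(A) tail, of short transcripts and of the gene lists across splits.

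Other gene groups, chosen after the main results were seen, include parts of protein synthesis. Their camera p-values are adjusted over these 8 groups alone, so they are not on the scale of the 31 fixed lists, of which 0 passed with an estimated correlation (4 at an unadjusted p under 0.05). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 15 fell, led by GARS1 from 653 to 255 mean CPM. Camera gave adjusted p = 1.53e-07, and adjusted p = 0.034 with an estimated correlation. GARS1, WARS1, AARS1 and SARS1 are also members of the fixed integrated stress response list, so this group is not a separate result from that list. Of 29 translation initiation and elongation factors 22 fell (camera adjusted p = 3.62e-08, and 0.034 with an estimated correlation). EEF2, an elongation factor, went from 7730 to 4510 mean CPM and EIF4A2 from 353 to 172. Of 22 small nucleolar RNA host genes 17 fell, including SNHG7, which fell by 1.37 on the log2 scale with up to 22.7% of its reads open to an opposite-strand gene, and SNHG32, which fell by 1.09 (camera adjusted p = 3.61e-08, and 0.071 with an estimated correlation). Of 31 proteasome subunit genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom.

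Of 22 interleukin and chemokine receptor genes 10 rose, 1 fell and 11 did not pass the test (camera adjusted p = 0.000181, and 0.034 with an estimated correlation), with CXCR3 going from 0.284 to 6.61 mean CPM and IL4R from 9.99 to 33.7. Of 28 lysosomal genes 6 rose and 2 fell (camera adjusted p = 0.0582), and of 16 class I antigen presentation genes 3 rose and 1 fell (camera adjusted p = 0.559).

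Transcripts of 270 genes were present in 5 libraries and missing from AraC replicate 2. Low depth is argued against, since this was the deepest library and it held 706 reads over these genes where 29864 were expected, or 2.36%. Loss after AraC is argued against, since their median level in the other AraC libraries was at least 0.787 of the mean over the 5 libraries. RNA of another cell source may have entered the other 5 libraries: of 12 detected neural markers 10 are missing from AraC replicate 2 (NES reached 12.44 CPM elsewhere), as are 3 of 8 melanocyte markers and 5 of 823 detected genes of the fixed lists. This stays open because the marker lists were written after the genes were seen, and the G0/G1 sort, set by DNA and RNA content, would not by itself exclude such cells.

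Of 23 lymphocyte markers 10 could be tested and 8 rose after AraC, in cells sorted from a myeloid line. Lymphocytes among the sorted cells are argued against, since of 8 abundant lymphocyte transcripts 7 stood below 5% of the TRAC level and MS4A1, IGKC and IGHM had 0 reads. However, CD3D, TRBC2 and CD3E stood near that cutoff (5.36%, 4.82% and 3.92%). CD3D and CD3E also rose with TRAC (log2 1.83 and 1.77), while TRBC2 did not pass the test. B-cell precursors are argued against in the same way, with 5 of 8 transcripts below 5% of the PAX5 level and VPREB1 and DNTT at 0 reads, although CD22 and BLNK rose (log2 1.88 and 2.55). The RNA source missing from AraC replicate 2 is argued against, since the 10 tested markers stood in that library at a median of 0.84 (0.528 to 1.22) of their mean in the other 2 AraC libraries. No biological explanation was tested.

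Of 24 replication-dependent histone genes tested 12 fell and 12 did not pass the test, with a median of -1.48 over the 24. Fewer S-phase cells as the whole cause stays open. It predicted that the G1/S genes would fall too, and their median was 0.29. That list also covers genes of S-phase entry, so it does not measure the share of S-phase cells. Loss of short transcripts was tested on 134 other protein-coding genes with 1 exon record and 397 to 4265 bases, the histone range. Their median was -0.12, above -0.74, which is 0.5 of the histone median. This argues against a general loss of single-exon transcripts in that range. It does not test the shortest ones apart, and H2BC13 and H2AC8 are 451 and 517 bases long. Less carry-over of RNA without a poly(A) tail cannot be told apart from a change in the cells, because only 2 such RNAs could be tested (RN7SL1 0.44, RMRP -0.67, median -0.12). A block of DNA synthesis by AraC may lower these transcripts, which was not tested.

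The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4822 genes and the highest of the others 0 (605 at an unadjusted p under 0.05, and at most 2 by DESeq2 in any other split), and for genes changed at least 2-fold 1164 and 0. Only 1 of the 10 splits, the real split, reached these numbers. In the other splits the AraC difference adds to the spread within each side, which lowers the gene calls. Their counts therefore do not show how many genes would be called without a difference. For gene lists by the preset camera the real split called 13 and the highest of the others 15, and 3 of the 10 splits called at least 13. Each other split sets 2 libraries of a treatment with 1 of the other on both sides, so part of the AraC difference stays in it and the lists called there are not calls without a difference.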
